A study of Mus musculus with 9 samples.

How the data were processed

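Gene expression was measured in stomachs of newborn mice, 5 with a knockout of the C/EBPβ gene and 4 wild type, with 1 array per mouse. Per the labels, the mice were killed at birth, total RNA was extracted with a commercial kit and treated with DNase I, and 0.3 µg of it was copied from oligo dT primers and labelled with Cy3, so each array carries 1 colour. The labels' source field calls the mice old, whereas their treatment protocol and the series' design place them at birth, and the mice are called newborn here. The labels give each sample the number of a separate mouse in its group. They state neither the strain nor which part of the gene was removed.

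The scanner values are spot intensity on a linear scale, and per the file headers the authors made them with an Agilent scanner and Feature Extraction 10.5.1.1 (1-colour protocol GE1_107_Sep09) for a mouse array design annotated on mouse build mm9. The submitters' processing notes name Feature Extraction 9.1 instead. Per the file headers, the processed signal intensity had its background subtracted with a spatial detrend and dim spots replaced by surrogate values, and was not normalized between arrays. The deposited files also hold yes or no flags of another kind per spot, namely well above background, saturated and outlier, as Feature Extraction set them. The authors' series matrix holds log2 values of the same arrays. Differences between arrays in that matrix followed log2 of the processed signal with a largest deviation of 3.61e-06 over 24308 probes, which settles its scale and direction, and all of its 55821 identifiers matched the arrays' probe names. What its probes were centred on stays unknown. The medians of its columns were 0.0436, 0.217, −0.124, 0.0347 and −0.137 for KO 1 to KO 5 and −0.279, −0.161, 0.224 and 0.382 for WT 1 to WT 4.

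Each array has 62976 spots, of which 3671 are controls and were left out. The 59305 others read 55681 probes, 432 of them with more than 1 spot. Spots with an outlier flag were left out and the spots of a probe were averaged, which left 21 probes without a value on some array because their spot had such a flag. Between 50.9% and 57.2% of the spots were well above background per array and 0 were saturated. The number of arrays limits the precision. Gene names are those of the array design. Through its accession, 26756 probes matched the RefSeq table of assembly GRCm38.p6, used for names only, and 2877 of them took another name there. Coordinates are those of the array design on mm9. A genome sequence was not used here.

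The value analysed was log2 of the processed signal minus the array's 75th percentile of it. Probes well above background on at least 4 of the 9 arrays were kept (30191), and each gene was read from its probe with the highest mean, which gave 21724 genes, 7047 of them without a gene symbol. Knockout and wild type were compared with limma 3.58.1 (lmFit and eBayes, two-sided) in R 4.3.3, with no covariate, Benjamini-Hochberg adjustment over the genes and a threshold of adjusted p below 0.05. For a gene, SE is limma's moderated standard error of the log2 difference. For a mean over a list, it is the unmoderated standard error of the difference between the groups, from the arrays' list means. A gene not well above background on any array of a group has only a bound there, given as "at least N-fold": the bright group's mean against the dim group's mean of, per array, the higher of the lowest signal among probes well above background and the probe's own signal. Single values were also tested with an exact two-sided permutation test over the 126 splits of the arrays into 5 and 4, whose smallest possible p is 0.00794.

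Before the data were examined, the design, the alternatives, 38 gene lists and the rule for naming genes were fixed. The lists cover the cell types of the newborn stomach, cell types and neighbouring organs that a dissected stomach can bring along, and cellular processes. The 37 lists with at least 4 tested members were tested with camera at a preset correlation between genes of 0.01, adjusted over the lists. The list of Y-linked and X inactivation genes had 3 tested members and served as a check of sex balance. Members past the threshold are counted over all genes tested and adjusted over the list alone. Camera with an estimated correlation, fry (whether a list moves one way on balance) and the exact permutation test of the arrays' list means were run beside it. The genes named are Cebpb and its family, the 12 genes with the largest rise and the 12 with the largest fall among those past the threshold whose groups do not overlap, leaving out sex-linked genes and genes without a proper symbol, and up to 4 members with the smallest p of each list called changed and of the gastric, squamous and proliferation lists. A gene outside this rule is said to have been chosen after its values were seen.

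The steps were tested on simulated data made from the 21724 genes' means and residual spreads, with 50 genes changed at each fold size. For this comparison they recovered 2% of genes changed 1.5-fold, 34% at 2-fold, 82% at 4-fold and 98% at 16-fold, with 6 false calls among 21509 unchanged genes. A shifted endothelium list was called at adjusted p = 5.86e-12 and 0 of the other lists were. That simulation holds no correlation between genes and no batch.

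The alternatives were normexp background correction (offset 50) of the raw mean signal, quantile normalization, median scaling, the series matrix values, no filter on dim probes, a filter on all 9 arrays, the mean of a gene's probes, the slide as a block, the replicate number as a block, array weights, a variance model with trend and robust settings, the Y-linked level as a covariate, and leaving out each array in turn. After the data had been seen, fits over the arrays with Y-linked signal only, within slide 1 and within slide 4 were added. Replicate numbers are mouse numbers and did not pair the groups.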

Results

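The data are gene expression profiles of newborn mouse stomach, 5 from knockout mice (KO 1 to KO 5) that lack C/EBPβ, a leucine zipper transcription factor encoded by Cebpb, and 4 from wild-type mice (WT 1 to WT 4). Each profile comes from 1 mouse and 1 Agilent 1-colour array. The 75th percentile of the processed signal ran from 221 on WT 4 to 472 on KO 3. The comparison asks which genes differ in the stomach at birth when C/EBPβ is missing.

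Knockout stomachs carried 2.26% of the wild-type Cebpb signal. Beside this loss, Gkn2 of gastric surface cells rose 3.45-fold and the cell surface proteoglycan gene Sdc4 9.56-fold, and H2-Eb1, a class II gene of the major histocompatibility complex (MHC), and Cd74, which encodes the invariant chain, rose too. The calcium-binding protein gene S100a9 and the antimicrobial gene Defb3 fell, and of the cornified envelope genes Sprr2h fell while Sprr2k rose. Of 11 granulocyte genes tested, S100a9 was the 1 that changed over all genes. With slide as a block, the genes named so far other than Cebpb lost their calls. By fitted change the largest fall after Cebpb was that of Gstp3 and the largest rise that of Krtap3-2. These kept their calls with the block (limma adjusted p = 0.0202 and 0.0340). As lists, pit and endocrine cell genes were higher and squamous differentiation, granulocyte and S phase genes lower by camera with its preset correlation, but none of these calls held with an estimated one (in that order, adjusted p = 0.248, 0.0907, 0.663, 0.102 and 0.477 with an estimated correlation). The wild-type array WT 4 stood apart from the other 3 wild-type arrays, and 3 knockout mice but no wild-type mouse lacked Y-linked signal.

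The targeted gene was read by 1 probe, which lies in the transcribed part of Cebpb on chromosome 2, 167515828 to 167515887 (mm9), from position 1413 of the transcript, with the sequence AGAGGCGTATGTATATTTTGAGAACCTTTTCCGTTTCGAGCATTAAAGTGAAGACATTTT. Cebpb has no introns. The processed signal was 44.0, 38.96, 158.5, 111.1 and 142.9 on KO 1 to KO 5 and 5394, 3161, 2892 and 1774 on WT 1 to WT 4. Relative to each array's 75th percentile, the log2 level was 3.50 ± 0.32 (SD, n = 4) in wild type and −1.97 ± 0.60 (SD, n = 5) in knockout. Cebpb fell by 5.47 ± 0.30 on the log2 scale (SE; 44.3-fold; limma adjusted p = 0.000131; exact permutation p = 0.00794), so every array carried the signal its genotype label calls for. The probe stayed well above background on all 9 arrays, and the sources used here do not say whether it lies in the part that was removed.

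The C/EBP family list, which contains the targeted gene, was called lower (6 members tested, mean log2 −0.88 ± 0.12 SE; camera adjusted p = 0.0321). Cebpb alone supplied that mean, as the other 5 members had a mean of 0.03 ± 0.10 SE (exact permutation p = 0.770), so the call restates the knockout. It was lost with an estimated correlation (adjusted p = 0.284 with an estimated correlation), without KO 1 (adjusted p = 0.0908), without WT 3 (0.0599) and without WT 4 (0.0878). Cebpb was the 1 member that changed, over all genes and adjusted over the list alone. Cebpd, an acute-phase relative, lay at 0.93 ± 0.51 (limma adjusted p = 0.666), Cebpa at −0.53 ± 0.37, the stress-induced Ddit3 at −0.36 ± 0.26, Cebpz at 0.30 ± 0.21 and Cebpg at −0.17 ± 0.16, and none of these passed the test. Cebpe, known from granulocyte maturation, was not well above background on any array.

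**Figure D1:**
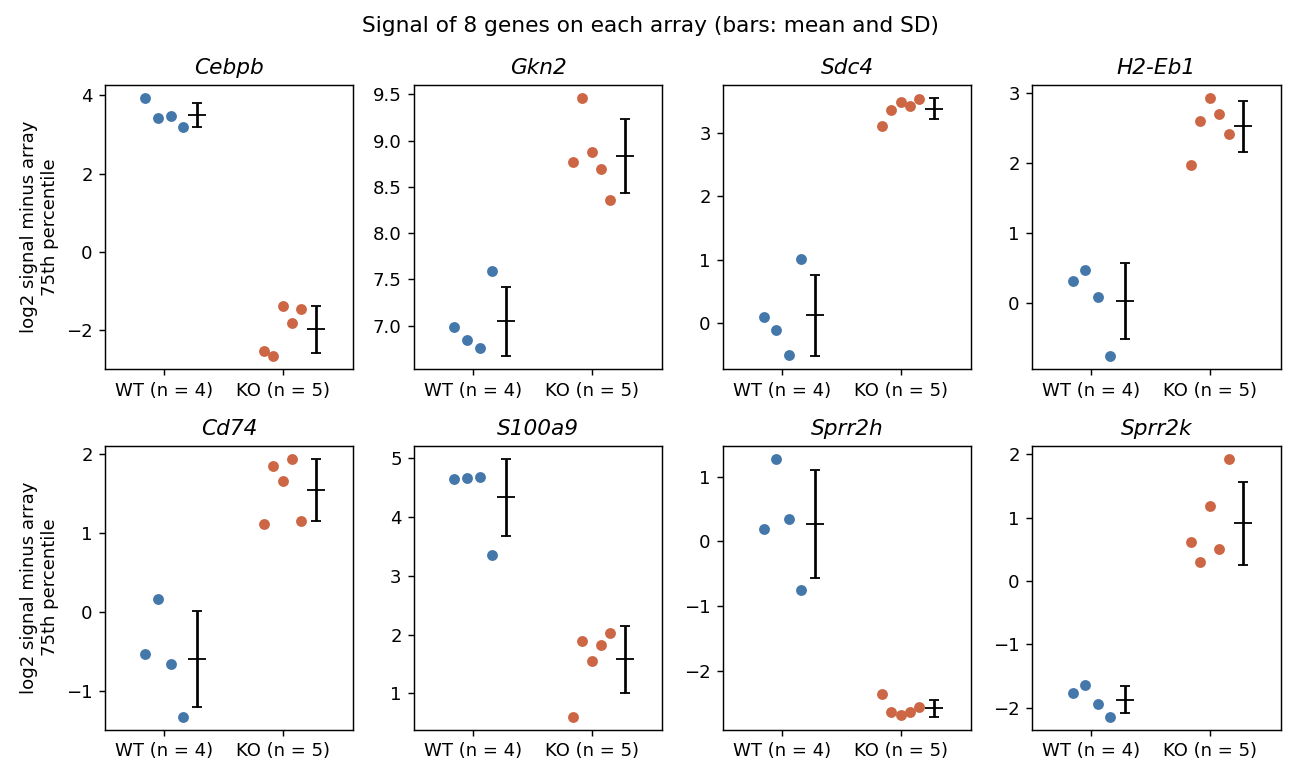
Log2 signal minus the array's 75th percentile (y axis) of 8 genes on each array, with 4 wild-type arrays in blue and 5 knockout arrays in orange, and black bars for the mean and SD. In each panel the 2 groups do not overlap, as for Cebpb with means of 3.50 in wild type and −1.97 in knockout.

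Over 21724 genes, 45 changed (28 rose and 17 fell, limma with Benjamini-Hochberg adjustment), 43 of them at least 2-fold (27 rose and 16 fell). At an unadjusted p below 0.05 there were 1921 genes, 1172 higher and 749 lower, against 1086 by chance. In all 45, the knockout arrays lay on one side of all wild-type arrays. This held for 738 genes in total, or 3.40%, where chance gives 1.59%. The median change of all genes was 0.0175.

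Among the genes that rose most were a pair of keratin-associated protein genes known from hair. Krtap3-2 was at least 11.7-fold higher (limma adjusted p = 0.00132) and Krtap3-3 at least 2.82-fold (adjusted p = 0.0495), neither being well above background on any wild-type array. Sdc4, which encodes the heparan sulfate proteoglycan syndecan-4 and was read on chromosome 2 at 164251211 to 164251270 (mm9), rose by 3.26 ± 0.27 (limma adjusted p = 0.00132). Sprr2k, a small proline-rich protein gene of cornifying epithelium, rose by 2.78 ± 0.31 and Cwh43, linked to lipid anchors of membrane proteins, by 2.50 ± 0.23. H2-Eb1, an MHC class II chain, rose by 2.49 ± 0.28 (limma adjusted p = 0.0107) and Cd74, the invariant chain that class II molecules need, by 2.13 ± 0.30 (limma adjusted p = 0.0275). Cd209a, a lectin of dendritic cells, was at least 1.80-fold higher (limma adjusted p = 0.0126). Bnip5 (2.57 ± 0.37, well above background on 1 of 4 wild-type arrays, so its size is uncertain), the carboxylesterase gene Ces2a (1.81 ± 0.26), the crystallin gene Cryaa (1.79 ± 0.23, on 3 of 4) and Gkn2, which encodes a secreted protein of gastric surface cells (1.79 ± 0.25, limma adjusted p = 0.0252), completed the 12 largest rises by fitted change. The rank of Krtap3-3 and Cd209a is uncertain, as their wild-type signal was not well above background.

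By fitted change, the largest falls after Cebpb were those of Gstp3, a glutathione S-transferase gene, at least 5.54-fold (limma adjusted p = 0.000137), and of Defb3, a beta-defensin gene, at least 4.79-fold (adjusted p = 0.00132). Neither was well above background on any knockout array, so their rank is uncertain. Sprr2h, a relative of Sprr2k from the same family, fell by 2.85 ± 0.33 (limma adjusted p = 0.0114). S100a9, a calcium-binding protein gene abundant in neutrophils, fell by 2.75 ± 0.36 (limma adjusted p = 0.0179). Slc5a5, the sodium iodide symporter gene, fell by 2.24 ± 0.29, the surfactant protein gene Sftpd by 1.84 ± 0.20 and Nppa, the atrial natriuretic peptide gene, by 1.59 ± 0.18. Tdh, the threonine dehydrogenase gene, fell by 1.46 ± 0.17, Trp53rka by 1.32 ± 0.20, Pusl1 by 1.16 ± 0.16 and C1qtnf12 by 0.87 ± 0.14, the last with a limma adjusted p of 0.0495. Cptp fell by 1.64 ± 0.21, while another probe of it read −4.36, so its probes differ in size. Members of the Sprr2, Krtap3, Ces2, Gstp and Defb families resemble each other in sequence, so a probe can also have bound a relative, and these assignments are uncertain.

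Of the cell types of the glandular stomach, pit, mucous neck, endocrine and parietal cells had lists that were higher, while the chief cell list did not change. None of these 4 calls held with an estimated correlation (in that order, adjusted p = 0.248, 0.352, 0.0907 and 0.477 with an estimated correlation). All 15 pit cell genes tested, the markers of the mucous surface cells, were higher (mean 0.91 ± 0.24 SE; camera adjusted p = 2.92e-11; adjusted p = 0.248 with an estimated correlation). Of the 15, Gkn2 rose over all genes and 10 rose adjusted over the list alone, among them Capn9 (1.46 ± 0.25), Gkn1 (1.85 ± 0.36) and Sult1c2 (1.14 ± 0.26). The list mean of each of the 5 knockout arrays lay above all wild-type arrays (exact permutation p = 0.00794), but WT 4, at 0.64 relative to the wild-type mean, lay just under the lowest knockout array at 0.65. Of 9 mucous neck cell genes 8 were higher (mean 0.64 ± 0.23; camera adjusted p = 0.00172; adjusted p = 0.352 with an estimated correlation). None changed over all genes, and adjusted over the list alone the water channel gene Aqp5 (2.04 ± 0.40), Tff2 (0.66 ± 0.17) and the mucin gene Muc6 (1.02 ± 0.31) rose and Wfdc2 fell (−0.82 ± 0.26).

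Of 17 gastric endocrine cell genes tested, 16 were higher (mean 0.76 ± 0.13; camera adjusted p = 6.32e-09; adjusted p = 0.0907 with an estimated correlation). None changed over all genes, while 8 rose adjusted over the list alone, including Hdc, the histamine-forming enzyme gene (0.87 ± 0.19), and the secretory granule genes Chgb (1.27 ± 0.31) and Chga (0.75 ± 0.20). All 5 knockout arrays lay above all wild-type arrays for this list.

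Parietal cell genes, which serve acid secretion, were higher in 13 of 16 (mean 0.28 ± 0.14; camera adjusted p = 0.00126; adjusted p = 0.477 with an estimated correlation), with Slc26a9 at 0.74 ± 0.20 and Kcnq1 at 0.56 ± 0.19. General epithelial genes were likewise higher in 13 of 16 (mean 0.28 ± 0.14; camera adjusted p = 0.00714; adjusted p = 0.477 with an estimated correlation), and that call was lost without WT 3 (mean 0.20; adjusted p = 0.0726). In neither list did a member change over all genes or adjusted over the list alone. The 9 chief cell genes did not change as a list (mean 0.14 ± 0.14; camera adjusted p = 0.587), nor did the 27 gastric transcription factor and progenitor genes (mean 0.12 ± 0.15; camera adjusted p = 0.498). Sox2, a factor of foregut epithelium on the latter list, lay at −1.03 ± 0.18, which did not pass over all genes (limma adjusted p = 0.0811) but did adjusted over the list alone.

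Of 43 genes of squamous differentiation in the forestomach, the keratinised part of the mouse stomach, 31 were lower and 12 higher (mean −0.61 ± 0.57; camera adjusted p = 0.000302; adjusted p = 0.663 with an estimated correlation). Sprr2h was the 1 member that fell over all genes and adjusted over the list alone, and Calm4 lay at −3.05 ± 0.88, Lce3c at −2.18 ± 0.65 and Il1f9 at −2.34 ± 0.72. The array means did not separate the genotypes (exact permutation p = 0.333), since WT 4 lay at −1.48 relative to the wild-type mean and KO 5 at −1.66. The mean change was −1.10 without WT 4 and −0.34 without KO 5. The 14 squamous basal cell genes did not change as a list (mean −0.055 ± 0.12; camera adjusted p = 0.860), with Pdpn at −0.99 ± 0.36.

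**Figure D2:**
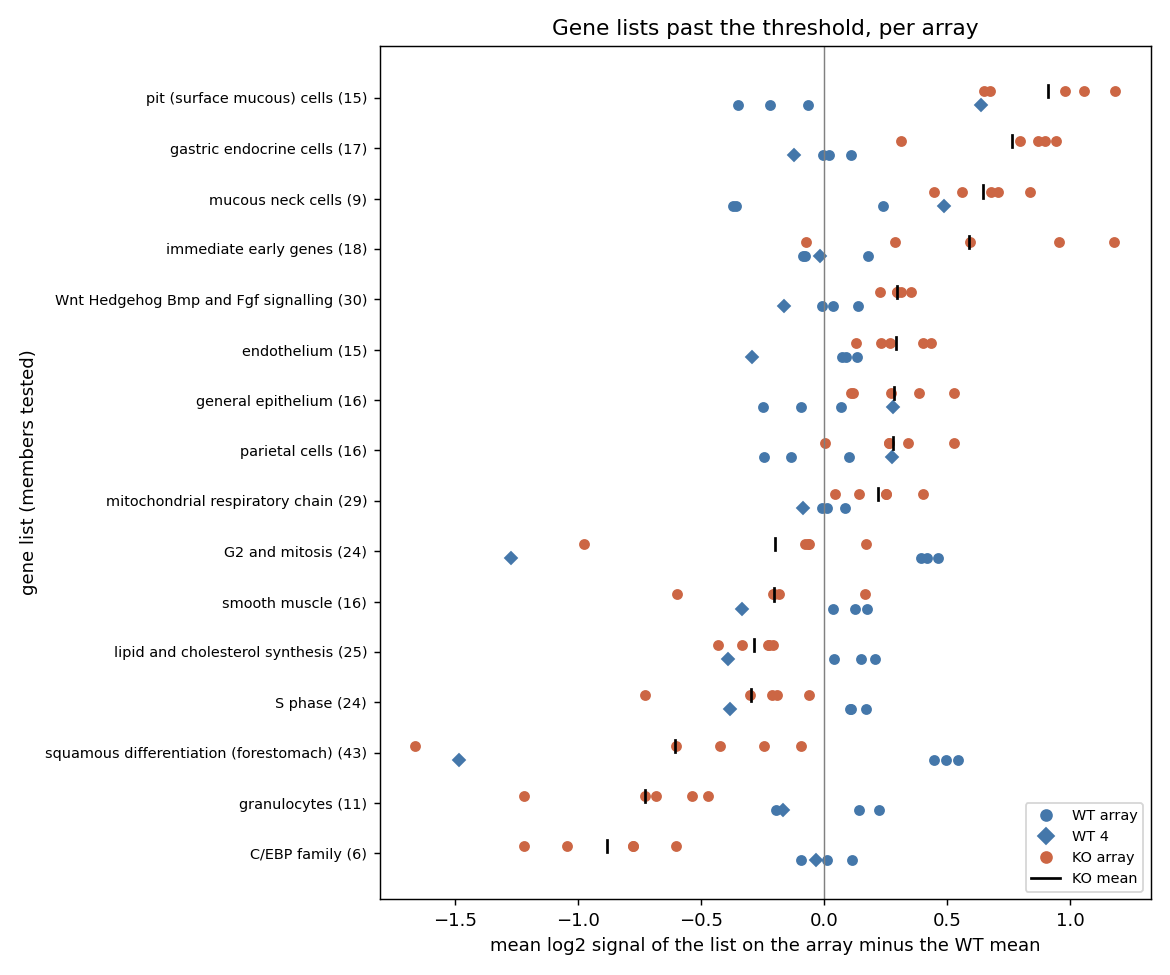
Mean log2 signal of each of the 16 gene lists past the threshold on each array, minus the wild-type mean (x axis), with wild-type arrays in blue (WT 4 as a diamond), knockout arrays in orange and a black line for the knockout mean. For pit cell genes all 5 knockout arrays lie above all wild-type arrays, while for squamous differentiation genes WT 4 lies at −1.48 and the genotypes overlap.

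Granulocyte genes were lower in 8 of 11 (mean −0.73 ± 0.17; camera adjusted p = 0.00172; adjusted p = 0.102 with an estimated correlation). S100a9 fell over all genes, and adjusted over the list alone also the protease inhibitor genes Stfa1 (−2.12 ± 0.63) and Stfa2 (−1.78 ± 0.52), while Mpo, the myeloperoxidase gene of granule formation, lay at −0.62 ± 0.43. Apart from the 3 that fell, the members lay between −0.65 and 0.33, with Ltf at 0.33 ± 0.50, Camp at 0.17 ± 0.44, S100a8 at 0.12 ± 0.33 and Elane at −0.11 ± 0.21, named after their values were seen. Which cells carried the 3 that fell was not tested. Within wild type, S100a9 (3.35) and Stfa1 (2.02) were lowest on WT 4, as was the squamous differentiation list. Within knockout, KO 5 was lowest for that list but highest for S100a9 (2.03). All 5 knockout arrays lay below all wild-type arrays (exact permutation p = 0.00794). Endothelial genes were higher in 13 of 15 (mean 0.29 ± 0.11; camera adjusted p = 0.00208; adjusted p = 0.290 with an estimated correlation), and the call was lost without WT 4 (mean 0.19; adjusted p = 0.0740) and over the arrays with Y-linked signal (mean 0.18; adjusted p = 0.155). Smooth muscle genes were lower in 13 of 16 (mean −0.21 ± 0.17; camera adjusted p = 0.00714; adjusted p = 0.563 with an estimated correlation). Adjusted over the list alone, the actin gene Actg2 fell (−0.92 ± 0.21) and Pcp4 rose (1.31 ± 0.32). The smooth muscle call was lost without KO 2 (mean −0.11), WT 1 (−0.16) or WT 3 (−0.15), and the mean was −0.32 without WT 4.

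S phase genes, which serve DNA replication, were lower in 23 of 24 (mean −0.30 ± 0.17; camera adjusted p = 1.48e-05; adjusted p = 0.477 with an estimated correlation), and the mean was −0.19 without KO 5. Ung, a DNA repair gene, lay at −0.81 ± 0.25 and Cdc45 at −0.63 ± 0.22. Genes of G2 and mitosis were lower in 20 of 24 (mean −0.20 ± 0.47; camera adjusted p = 0.0401; adjusted p = 0.828 with an estimated correlation), with Hmmr at −0.45 ± 0.23 and Aurka at −0.40 ± 0.33. That mean followed single arrays. It was −0.63 without WT 4, which lay at −1.27 relative to the wild-type mean, and the call was lost without KO 3 (mean −0.0079), WT 1 (−0.047), WT 2 (−0.070) or WT 3 (−0.062). No member of the S phase or mitosis lists changed over all genes or adjusted over the list alone.

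Immediate early genes, transcribed within minutes of a stimulus, were higher in 16 of 18 (mean 0.59 ± 0.23; camera adjusted p = 3.87e-05; adjusted p = 0.477 with an estimated correlation), with Fos at 1.36 ± 0.40 and Egr1 at 1.15 ± 0.39. Their list mean was highest on KO 4 (1.18) and KO 5 (0.95), both without Y-linked signal and both on slide 1. KO 2, also without that signal, lay at 0.29, below KO 3 (0.59), which carried it. The call was lost with the Y-linked level as a covariate (mean 0.18; camera adjusted p = 0.343). Over the arrays with Y-linked signal it was kept at a smaller mean (0.26; adjusted p = 0.0355). Mitochondrial respiratory chain genes were higher in 28 of 29 (mean 0.22 ± 0.07; camera adjusted p = 5.16e-06; adjusted p = 0.477 with an estimated correlation), with Uqcrfs1 at 0.47 ± 0.18. Genes of lipid and cholesterol synthesis were lower in 21 of 25 (mean −0.28 ± 0.14; camera adjusted p = 0.000333; adjusted p = 0.477 with an estimated correlation), with Scd1 at −1.06 ± 0.40. Wnt, Hedgehog, Bmp and Fgf signalling genes were higher in 23 of 30 (mean 0.30 ± 0.07; camera adjusted p = 0.00164; adjusted p = 0.102 with an estimated correlation), with the Hedgehog target Gli1 at 0.68 ± 0.16, and the call was lost without WT 4 (mean 0.24; adjusted p = 0.0546). In these 4 lists no member changed over all genes or adjusted over the list alone.

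In all, 16 of the 37 lists changed, 9 up and 7 down, by camera with the preset correlation, the C/EBP family with its targeted gene among them. With an estimated correlation 0 of the 37 passed (lowest adjusted p = 0.0907; 6 at an unadjusted p below 0.05). Fry called 3, namely the C/EBP family, whose call rests on Cebpb itself, endocrine cells and Wnt, Hedgehog, Bmp and Fgf signalling (8 at an unadjusted p below 0.05), and the exact permutation test of list means called 0 after adjustment (8 at an unadjusted p below 0.05).

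The other lists did not pass by camera over all arrays. The adjusted p was 0.0509 for fibroblasts and matrix, 0.0706 for interstitial cells of Cajal and the enteric nervous system, 0.0882 for the interferon response, 0.187 for erythroid cells and for cell cycle inhibitors and p53 targets, 0.277 for the unfolded protein and amino acid stress response, and 0.498 for macrophages and general leukocytes and for fasting and fatty acid oxidation. It was 0.619 for EGF receptor ligands and receptors. In 4 lists the mean and the median differed in sign, namely mast cells (mean 0.14, median −0.35, adjusted p = 0.505), lymphocytes (0.039 and −0.012, 0.860), inflammatory cytokines and acute phase (−0.057 and 0.0052, 0.663) and hypoxia and glycolysis (0.095 and −0.019, 0.674). Of tissues that can come along in a dissection, intestine and skeletal muscle had an adjusted p of 0.189, adipose tissue of 0.314, liver of 0.381 (mean −0.56 ± 0.91) and pancreas of 0.778. Adjusted over the list alone, Hdc and Mcpt2 of the mast cell list, Hbb-b2 of the erythroid list and Iapp of the pancreas list rose, and Cela3b of the pancreas list and Reg3g of the intestine list fell, none of them past the threshold over all genes. Cidec, a lipid droplet gene on the adipose list, rose by 0.97 ± 0.15 over all genes. These members were named after their values were seen.

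Some of these lists passed when 1 array was left out. Fibroblast and matrix genes were called higher when any 1 of KO 1, KO 2, KO 3, KO 5, WT 1, WT 2 or WT 3 was left out (mean 0.24 to 0.39; camera adjusted p = 0.00223 to 0.0412), but not without KO 4 (0.11; 0.458), and their mean turned without WT 4 (−0.10; 0.387). Interferon response genes were called higher without KO 3, KO 5 or WT 1 (mean 0.25, 0.29 and 0.30), erythroid genes without KO 3 (0.37), and genes of interstitial cells of Cajal and the enteric nervous system without KO 2 (0.32) or KO 5 (0.17). Liver genes were called lower without KO 2 (−1.07), and skeletal muscle genes without KO 4 (−0.36) or WT 4 (−0.69).

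WT 4 was the array farthest from the rest. It lay at −91.2 on the first principal component, which holds 34.8% of the variance, where the other arrays ran from −32.6 to 39.5, and its residual SD was 0.891 against 0.430 to 0.544 on the others. Relative to the wild-type mean it was at −1.99 for mast cell, −1.46 for skeletal muscle, −1.01 for matrix and 1.85 for liver genes. WT 4 also had the lowest slope of the fit to the spike-in controls, 0.925 against 0.975 to 1.02 on the others. Its 75th percentile of the processed signal was the lowest too (221). Whether its distance is technical or lies in the tissue was not tested. Without WT 4, 149 genes changed (86 rose and 63 fell), including all 45, and 14 lists did, including 13 of the 16 and skeletal muscle, by camera with the preset correlation. With an estimated correlation the lowest adjusted p over the lists was 0.156 without WT 4.

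**Figure D3:**
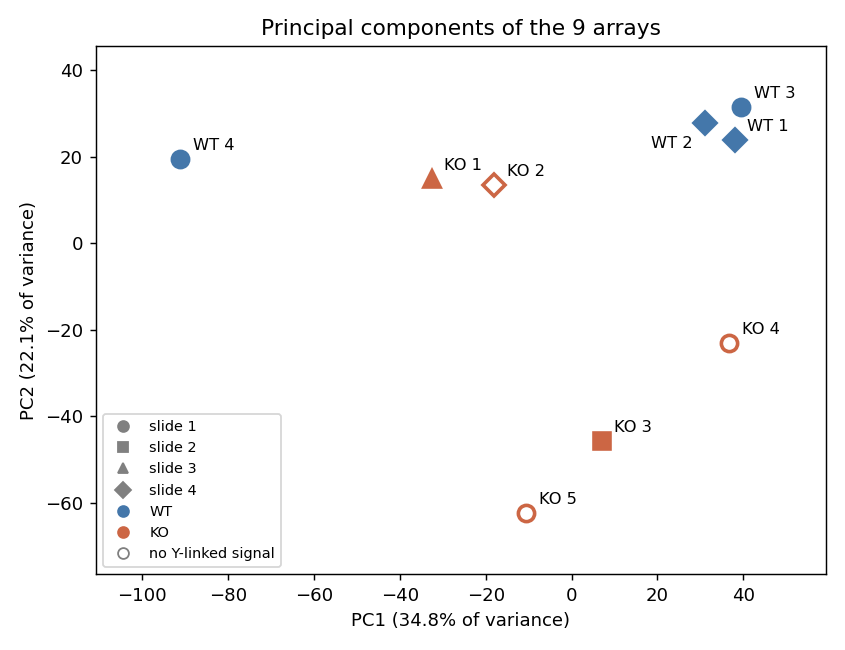
First and second principal components of the 9 arrays over 21724 genes (34.8% and 22.1% of the variance), with wild type in blue, knockout in orange, open symbols for arrays without Y-linked signal and a symbol shape per slide. WT 4 lies at −91.2 on the first component, away from the other 3 wild-type arrays.

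The groups also differed in sex. Y-linked genes were read on all 4 wild-type arrays and on KO 1 and KO 3, and Xist was well above background on KO 2, KO 4 and KO 5 alone. Of the Y-linked genes, Eif2s3y was also weakly above background on KO 2 (−3.15 on the log2 scale). Over the 6 arrays with Y-linked signal all 45 genes kept their sign, which was fixed in advance because their genotypes do not overlap. They changed at a median of 0.992 times their change over all arrays (0.741 to 1.19 times), but 4 genes passed, 3 of them among the 45. The knockout arrays in this fit, KO 1 and KO 3, share no slide with a wild-type array, so it does not separate genotype from slide. Of the lists, endothelium lost its call over these arrays, and interstitial cells of Cajal and the enteric nervous system (mean 0.35; camera adjusted p = 0.00152) and liver (−1.26; 0.00304) gained one. The liver mean had the opposite sign within slide 4 (1.99). The arrays lay on 4 slides. Slide 1 held KO 4, KO 5, WT 3 and WT 4, slide 4 held KO 2, WT 1 and WT 2, and slides 2 and 3 held 1 knockout array each. With slide as a block, Cebpb fell by 5.51 (limma adjusted p = 0.00988), and within slides 1 and 4 it fell by 4.97 and by 6.33. With that block 5 genes passed, 4 of them among the 45. Of the genes named for their size, Gstp3 (limma adjusted p = 0.0202) and Krtap3-2 (0.0340) kept the call with Cebpb, while Sdc4 (0.0789), H2-Eb1 (0.0789), Defb3 (0.0933), Cwh43 (0.142) and Gkn2 (0.297) were among those that lost it. All 45 kept their sign with the block and within both slides, at a median of 1.01 times their change with the block. Their sign could not turn in these fits, as their genotypes do not overlap on any array. Slides 2 and 3 hold no wild-type array, so the block takes up KO 1 and KO 3. What remains sets KO 2, KO 4 and KO 5, all without Y-linked signal, against wild-type arrays that all carry it. The block and within-slide fits therefore do not separate genotype from sex.

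With slide as a block, then within slide 1, then within slide 4, the mean list changes were 0.96, 0.71 and 1.33 for pit cells, 0.68, 0.63 and 0.75 for mucous neck cells, and 0.69, 0.98 and 0.25 for endocrine cells. In that order they were 0.29, 0.12 and 0.54 for parietal cells, 0.30, 0.31 and 0.29 for general epithelium, −0.60, −0.41 and −0.89 for squamous differentiation, and −0.56, −0.64 and −0.45 for granulocytes. They were 0.38, 0.53 and 0.16 for endothelium, −0.33, −0.26 and −0.44 for S phase, 0.76, 1.12 and 0.23 for immediate early genes, −0.27, −0.039 and −0.61 for lipid synthesis, 0.26, 0.20 and 0.35 for the respiratory chain, 0.32, 0.38 and 0.23 for Wnt, Hedgehog, Bmp and Fgf signalling, and −0.84, −0.73 and −1.01 for the C/EBP family. Smooth muscle genes turned within slide 1 (−0.24, 0.060 and −0.68), and G2 and mitosis genes turned with the block and within slide 1 (0.093, 0.48 and −0.49), where they passed in the opposite direction (camera adjusted p = 0.0206). With the block the calls of the C/EBP family (camera adjusted p = 0.121) and of G2 and mitosis (adjusted p = 0.713) were lost, and those of fibroblasts and matrix (mean 0.36; camera adjusted p = 0.0106), the interferon response (0.31; 0.0136) and erythroid cells (0.40; 0.0329) were gained.

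The count of changed genes moved with single arrays, to 10 without WT 1, 13 without WT 2, 14 without WT 3, 19 without KO 3, 23 without KO 4 and 28 without KO 2. Of the 24 genes with the largest rises and falls beside Cebpb, 5 (Krtap3-2, Sdc4, Cwh43, Gstp3 and Defb3) passed the test whichever array was left out, though Sdc4, Cwh43 and Defb3 did not with slide as a block. The call of Gkn2 was lost without KO 1, KO 3, KO 4, WT 1, WT 2 or WT 3 (limma adjusted p up to 0.106, log2 change 1.63 to 1.97 without any 1 array) and that of Cd74 without KO 2, KO 3, KO 4, WT 1 or WT 3 (up to 0.106, 1.89 to 2.38). That of S100a9 was lost without KO 3, KO 4, WT 1, WT 2 or WT 3 (limma adjusted p up to 0.0891, −3.08 to −2.51), those of Sprr2h and Sprr2k without WT 1 or WT 3 (up to 0.0635 and 0.0522) and that of H2-Eb1 without WT 3 (0.05).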

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

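No test in this part was chosen after the results were seen. Each value is the gap between the highest or lowest array of a genotype and its nearest neighbour, divided by the genotype's whole range, and is listed where it exceeds Dixon's critical value. Of 272 groups examined, 25 did so against 13.6 by chance, and 14 of the 25 lay on WT 4. Of these, 1 gene on WT 4 is not described here.

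Among genes, WT 4 was lowest in wild type for Cebpa (0.945), S100a9 (0.980), Il1f9 (0.928), Tagln (0.951), Kif11 (0.929) and Racgap1 (0.900), and highest for Cebpz (0.837). WT 1 was highest for Egr2 (0.928) and WT 2 was lowest for Gli1 (0.842). In knockout, KO 2 was highest for Tff2 (0.747) and Mpo (0.764), KO 4 was lowest for Chga (0.877), KO 5 was lowest for Calm4 (0.763) and E2f1 (0.849), and KO 3 was lowest for Aurka (0.740) and Racgap1 (0.712).

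Among list means, WT 4 was lowest in wild type for squamous differentiation (0.951), endothelium (0.860), macrophages and general leukocytes (0.882), S phase (0.882) and G2 and mitosis (0.960), and highest for pancreas (0.962). KO 2 was lowest in knockout for gastric endocrine cells (0.767) and KO 3 for G2 and mitosis (0.783).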

How the results depend on the processing

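The fits over the arrays with Y-linked signal and within slides 1 and 4 were chosen after seeing the data. Cebpb stayed past the threshold in every alternative but the one within slide 1, where it fell by 4.97 (limma adjusted p = 0.169), and without single arrays its change ran from −5.62 to −5.30. The 45 genes kept their sign in every alternative that tested them. For fits to part of the arrays, with a block, with array weights or with another variance model this was fixed in advance. In each of the 45 the genotypes do not overlap, so such fits cannot turn the sign. It could have turned only where values were processed differently or the Y-linked level was a covariate. The count was 25 (11 higher, 25 at least 2-fold) with no filter on dim probes, 5 (1 higher, 4 lower, 5 at least 2-fold) with slide as a block, 4 (1 higher, 3 lower, 4 at least 2-fold) with the replicate number as a block, 562 (330 higher, 232 lower, 296 at least 2-fold) with array weights, 6 (2 higher, 4 lower, 6 at least 2-fold) with the Y-linked level as covariate, 4 (2 higher, 2 lower, 4 at least 2-fold) over the arrays with Y-linked signal, and by limma 2 (0 higher, 2 lower, 2 at least 2-fold; 1299 at an unadjusted p below 0.05) within slide 1. Without single arrays it ran from 10 (WT 1) to 149 (WT 4), with 6 to 86 higher, 4 to 63 lower and 10 to 135 at least 2-fold. It was 13 without WT 2, 14 without WT 3, 19 without KO 3, 23 without KO 4 and 28 without KO 2. Of the lists, 16 changed by camera with the preset correlation, 0 with an estimated one, 3 by fry and 0 by exact permutation, with 6, 8 and 8 of them at an unadjusted p below 0.05. The other alternatives, apart from the fit within slide 4, gave 41 to 50 genes, but not always the same ones. Of the 45 genes, 32 were among the 41 with normexp, 33 among the 41 without KO 1 and 30 among the 42 without KO 5. All 45 recurred with the series matrix values. Over all lists and alternatives, 821 list results kept direction and side of the threshold, 82 lost the call, 44 gained one and 52 turned sign, against 2069, 229, 33 and 7 for the named genes. Within slide 4, with 1 residual degree of freedom, the lone knockout array is assumed to vary like the wild type. Fewer arrays or residual degrees of freedom enter the block, covariate, slide and left-out fits. For the other differences the cause was not tested. A block for the scan date was not run, as there was 1 date. Replicate numbers did not pair the arrays: the deviations of equally numbered knockout and wild-type arrays correlated across genes at −0.30, 0.12, 0.15 and −0.48, and genes are not independent replicates. Between 50.9% and 57.2% of the spots were well above background, which limits what dim genes can show.

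Values that turned sign follow, and the cause was not tested. Normexp: mast cells −0.14, lymphocytes −0.0090, pancreas −0.017. Median scaling: squamous basal cells 0.0019, inflammatory cytokines 0.00080. No filter: pancreas −0.022. All 9 arrays well above background: mast cells −0.15. Slide block: G2 and mitosis 0.093. Replicate block: fasting 0.017. Array weights: macrophages −0.13, mast cells −0.39, lymphocytes −0.0057, adipose tissue −0.0066, inflammatory cytokines 0.059, hypoxia −0.030. Y-linked covariate: squamous basal cells 0.023, fibroblasts −0.00077, macrophages −0.060, lymphocytes −0.051, intestine −0.20. Arrays with Y-linked signal: squamous basal cells 0.029, macrophages −0.0057, lymphocytes −0.038, intestine −0.14. Within slide 1: Aurka 0.019, Kif11 0.039, Racgap1 0.28, Clps −0.26, chief cells −0.00062, smooth muscle 0.060, lymphocytes −0.053, pancreas −0.030, skeletal muscle 0.42, G2 and mitosis 0.48. Within slide 4: Cebpg 0.12, Ddit3 0.31, Mpo 1.04, interstitial cells of Cajal −0.28, fibroblasts −0.25, macrophages −0.071, mast cells −0.16, intestine −0.0049, liver 1.99, EGF receptor ligands −0.073, unfolded protein response 0.050. Ranges without single arrays: squamous basal cells −0.15 to 0.00021, fibroblasts −0.10 to 0.39, macrophages −0.13 to 0.23, mast cells −0.52 to 0.45, lymphocytes −0.12 to 0.17, liver −1.07 to 0.056, skeletal muscle −0.69 to 0.089, inflammatory cytokines −0.14 to 0.073, fasting −0.22 to 0.022, unfolded protein response −0.15 to 0.0046.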

Other observations

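The tests on sex, on glandular mucosa and forestomach, on the MHC haplotype and on neighbouring genes were chosen after the results were seen, as were the class II list, the dendritic cell list and the genes named in the next 2 paragraphs.

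Class II antigen presentation genes were higher in all 8 members measured (mean 1.45 ± 0.33 SE; exact permutation p = 0.00794), and 7 of them rose adjusted over the list alone. The list was made because H2-Eb1 and Cd74 rose and holds both. The other 6 were all higher (mean 1.16 ± 0.34 SE; exact permutation p = 0.00794), none past the threshold over all genes by limma and 4 adjusted over these 6 alone. They were picked as genes of the same pathway after H2-Eb1 and Cd74 had been seen to rise, so this p-value is not independent support. Beside H2-Eb1 and Cd74, H2-Aa lay at 2.92 ± 0.55, H2-Ab1 at 1.24 ± 0.45 and H2-DMb1 at 1.15 ± 0.20, while H2-Ob lay at 0.14 ± 0.31. Muc13, a transmembrane mucin gene, rose by 1.41, Cd83, an activation marker of dendritic cells, by 1.35, and Foxf2, a forkhead factor gene of gut mesenchyme, by 1.21, each past the threshold over all genes.

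The hormone genes Gast (2.89 ± 1.05) and Sst (1.21 ± 0.39) of the endocrine list passed adjusted over the list alone and not over all genes. Reg3g, which encodes an antimicrobial lectin of the gut, lay at −4.20 ± 0.81 (limma adjusted p = 0.107) and fell adjusted over the intestine list alone. S100a8, whose product pairs with that of S100a9, lay at 0.12 ± 0.33 (limma adjusted p = 0.965) while S100a9 fell by 2.75.

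The rise of Sdc4 has a candidate explanation in strain DNA that came along with the targeted locus, since Sdc4 lies 3.27 Mb and the fallen Trp53rka 2.2 Mb from Cebpb. Within 10 Mb of Cebpb, 33 of 229 genes (14.4%) had an unadjusted p below 0.05 against 1876 of 21322 elsewhere (8.80%; two-sided Fisher's exact p = 0.00485), although neighbouring genes are not independent. The 33 include Sdc4 and Trp53rka themselves. Sex as the whole cause is argued against by a log2 change of 3.17 over the arrays with Y-linked signal. That value rests on KO 1 and KO 3, which share no slide with a wild-type array, so slide stays open there. Its sign was fixed in advance, as the genotypes do not overlap for Sdc4. A probe that reads another transcript stays open, as the array holds 0 other Sdc4 probes. An effect of C/EBPβ loss also stays open.

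The pit cell list was called higher by camera with the preset correlation, but not with an estimated one (camera adjusted p = 0.248), so chance is not excluded. The rise of pit cell genes may otherwise come from more glandular mucosa in the knockout samples, less forestomach, sex or the loss of C/EBPβ. More glandular mucosa of an unchanged cell make-up would raise pit and parietal genes alike, as far as parietal genes stand for that mucosa. The pit minus parietal list mean was 0.63 ± 0.14 SE (exact permutation p = 0.0238; 4 of 5 knockout arrays above all wild type; 0.75 without WT 4). This goes against that explanation as the whole cause. Both list means were known when the test was chosen, so the value does not decide. A mucosa whose make-up differed between the samples is not addressed by this value. For less forestomach as the whole cause the same value applies with the same limits, since a smaller share of forestomach then raises pit and parietal genes alike. More glandular mucosa and less forestomach therefore stay open, as the whole cause or as part of it. Squamous differentiation genes were lower (mean −0.61, −1.10 without WT 4 and −0.34 without KO 5). That call was lost with an estimated correlation (camera adjusted p = 0.663), and the exact permutation p was 0.333. Squamous basal genes went both ways (5 higher and 9 lower, mean −0.055). Sex as the whole cause is argued against by a mean of 0.83 over the arrays with Y-linked signal. That mean rests on KO 1 and KO 3, which share no slide with a wild-type array, so slide stays open there. Its sign was fixed in advance, as the list means of the genotypes do not overlap. The loss of C/EBPβ itself, and pit cells that differ in number or in content, stay open.

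The rise of class II genes may come from a different MHC haplotype on chromosome 17 or from more dendritic cells. Cd74 lies on chromosome 18, so its own DNA is not part of that haplotype. Its change of 2.13 was known when the test was chosen, so the value does not decide against the haplotype as an indirect cause. For the H2 genes (mean 1.35 ± 0.33 SE, with H2-Eb1 among them) the haplotype stays open, as the strain was not given in the sources used here. Dendritic cell markers outside the MHC had a mean of 0.21 ± 0.08 SE (exact permutation p = 0.0635; 8 of 13 higher), and 2, Itgax (0.98 ± 0.25) and Clec10a (0.83 ± 0.24), rose adjusted over the list alone. That mean plus 2 SE, 0.37, lies below 1.07, the bound used to argue against more dendritic cells, which is the Cd74 change divided by 2. The list was written after Cd209a and Cd83, dendritic cell genes that rose, had been seen, and it leaves both out. The bound therefore decides nothing, so more dendritic cells stay open, as does an effect of C/EBPβ loss.

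Of 100 splits of the arrays into 5 and 4, the real one included, 2 gave as many changed genes as the real 45 (highest other 76) and 2 as many at least 2-fold (real 43, highest other 65). Few splits thus reached either count, but these splits ignore the slides, and another split gave more than the real one. Chance is therefore not excluded for either count. With slide as a block, 5 genes passed. For the 16 lists, 6 of 100 gave as many (highest other 19), so chance cannot be excluded. The split with 76 genes exchanged KO 4 for WT 4, so these arrays carry a structure beside genotype. The split that sets slides 1 and 2 against slides 3 and 4 gave 38 genes, fewer than the real one but close to it.

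Of 44 changed genes with a position, 7 lay within 1 Mb of another, and 3 (C1qtnf12, Cptp and Pusl1, on chromosome 4) within 1 Mb of one from another gene family by name, where random sets of genes had a median of 2 such genes and a highest of 13. A share of 0.392 of 10000 random sets had as many, which leaves strain DNA elsewhere in the genome open.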
